A study of Mus musculus with 9 samples.

How the data were processed

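Messenger RNA was sequenced from primary mouse neural stem cells taken from the cortex at embryonic day 13.5 and kept in FGF (10 ng/mL) and EGF (20 ng/mL) on dishes coated with laminin (5 µg/mL). The cells carried a floxed Phf2 gene and were otherwise wild type. They were infected with virus carrying a non-targeting short hairpin RNA (shNT) or either of 2 hairpins against Rad21 (shRad21_1 and shRad21_2). Each of the 3 groups had 3 libraries, 9 in all. The labels do not state whether the libraries of a group come from separate cultures or animals. The p-values therefore measure the spread between libraries, which may be technical. The time between infection and harvest is not given in the sources used here.

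The deposited table holds counts per gene symbol, whole numbers in all 9 columns and not normalised. Per the submitters' processing notes, reads went through FastQC, cutadapt and Trim Galore, were aligned with Bowtie2 to the mouse build mm10 and were counted with RSEM. The versions of these tools, the gene annotation, the strand setting and the way RSEM estimates became whole numbers are not given in the sources used here. Of the 24503 gene rows, 6715 were 0 in all 9 libraries. Total counts ran from 34780003 to 46644607 per library, so that 3 counts corresponded to between 0.0643 and 0.0863 CPM (counts scaled to a common library total). Intervals on ratios of counts are exact Clopper-Pearson intervals at a confidence level of 0.95 and cover counting error only.

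Genes were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM scaling and filterByExpr by group, which left 13560 genes. All 9 libraries entered a single fit of 3 group means. The tests were two-sided, and a gene was called where its Benjamini-Hochberg adjusted p was under 0.05, with no minimum fold. The comparisons were each hairpin against shNT, shRad21_2 against shRad21_1, and the mean of both hairpins against shNT. Values per library are CPM on TMM-scaled totals, given as mean ± SD with n = 3 per group. Fold changes are log2 values with the standard error (SE) of the fit.

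The comparisons, the test, 25 lists of genes and the rule for naming genes were chosen before the data were examined. The rule named Rad21 and Phf2. It took the 12 higher and 12 lower genes called under both hairpins with the largest smaller fold, then the 5 higher and 5 lower with the largest fold under each hairpin, and the 8 higher and 8 lower between the hairpins. These genes needed a mean log2 CPM of at least 1 and groups that did not overlap in CPM. From each list it took the 4 members with the smallest p in the mean of both hairpins, or all members where 5 or fewer were tested. The rule gave 132 genes. Some genes outside it are named where 5 or fewer members of a list were called in a direction; these were chosen after their values were seen.

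Lists covered cohesin, condensin, DNA replication, mitosis, G1/S regulators, DNA repair, p53 targets, interferon-stimulated genes, inflammatory genes, the stress response, immediate early genes, cholesterol synthesis, clustered protocadherins, Hox genes and the PHF2 family with H3K9 methylation. Marker sets covered neural stem cells, neurons, astrocytes, the oligodendrocyte lineage, microglia, endothelium and mesenchyme. A further group covered mitochondrially encoded genes, cytoplasmic ribosomal proteins and replication-dependent histones. Each list was counted over all genes tested and adjusted over the list alone, and tested with camera (limma 3.58.1, correlation preset at 0.01), adjusted over the 23 lists with enough tested members. Camera was run again with an estimated correlation, under which 0 of the 23 lists passed in any of the 4 comparisons. At an unadjusted p with the estimated correlation, 0 lists passed for either hairpin against shNT and for the mean, and 2 passed between the hairpins. Fry, which tests whether the genes of a list move on balance in a single direction, called 0 lists for shRad21_1, 11 for shRad21_2, 15 between the hairpins and 3 for the mean.

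On simulated data with 200 changed genes among 13560, the edgeR test recovered 89.6% of 2-fold changes for shRad21_1 and 86.6% for shRad21_2, with 11 and 8 unchanged genes called. The simulated libraries were independent draws, and the changed genes were not taken from the lowest counts. Close pairs of libraries, as found in these data, were not simulated. These values therefore do not bound the false calls in the real data. Alternatives were DESeq2 1.42.0 size factors, library totals without a composition factor, the DESeq2 Wald test, limma-voom, looser and stricter filters, a floor of 1 on the absolute log2 fold change, fits of 2 groups, a replicate block, fry, and each library left out in turn. Fits with close pairs of libraries summed, and without the first libraries of shNT and shRad21_1, were added after the data were seen. Gene positions came from GENCODE for the same build, matched by symbol for 13033 of the 13560 genes (96.11%). Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.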

Results

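Transcript counts were compared between mouse neural stem cells carrying a non-targeting hairpin (shNT) and cells carrying either of 2 hairpins against Rad21, the kleisin subunit of the cohesin ring. Each group had 3 libraries. Total counts in replicates 1, 2 and 3 were 35646421, 41492296 and 44248371 for shNT. They were 36786416, 36954415 and 37014766 for shRad21_1, and 46644607, 34780003 and 36437848 for shRad21_2. The 10 genes with the most counts took between 3.77% and 4.61% of a library. Counts on the ribosomal RNA gene Rn45s took 0.483% of shRad21_2 replicate 1 and between 0.0552% and 0.114% of the others. No gene of the mitochondrial genome had an entry in the table, so the list of mitochondrially encoded genes had 0 members.

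Rad21 mRNA was lower in all 6 knockdown libraries than in all 3 shNT libraries. The gene (ENSMUSG00000022314.10) lies on chromosome 15 from 51962240 to 51991747 of mm10. Its level was 531, 450 and 456 CPM in the shNT libraries (479 ± 45.0, SD, n = 3). It was 187, 174 and 178 CPM with shRad21_1 (180 ± 6.92, n = 3) and 82.0, 91.2 and 82.5 CPM with shRad21_2 (85.3 ± 5.19, n = 3). Rad21 fell by 1.41 on the log2 scale under shRad21_1 (SE 0.09, edgeR adjusted p = 1.66e-04) and by 2.49 under shRad21_2 (SE 0.09, adjusted p = 2.83e-07). The hairpins differed from each other by a log2 fold change of -1.08 (SE 0.09, adjusted p = 5.55e-05), with shRad21_2 the lower. Phf2, the gene carrying the floxed allele, stood at 146 ± 5.13 CPM in shNT, 191 ± 5.00 with shRad21_1 and 197 ± 13.3 with shRad21_2 (n = 3 each). It rose by 0.44 under shRad21_2 (SE 0.07, edgeR adjusted p = 0.00101) and by 0.39 under shRad21_1 (SE 0.07, adjusted p = 0.00971). The call under shRad21_1 was lost without shNT replicate 2 (0.37, adjusted p = 0.0609) or replicate 3 (0.38, adjusted p = 0.0552), within a range of 7.22e-05 to 0.148 over 16 alternatives.

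**Figure D1:**
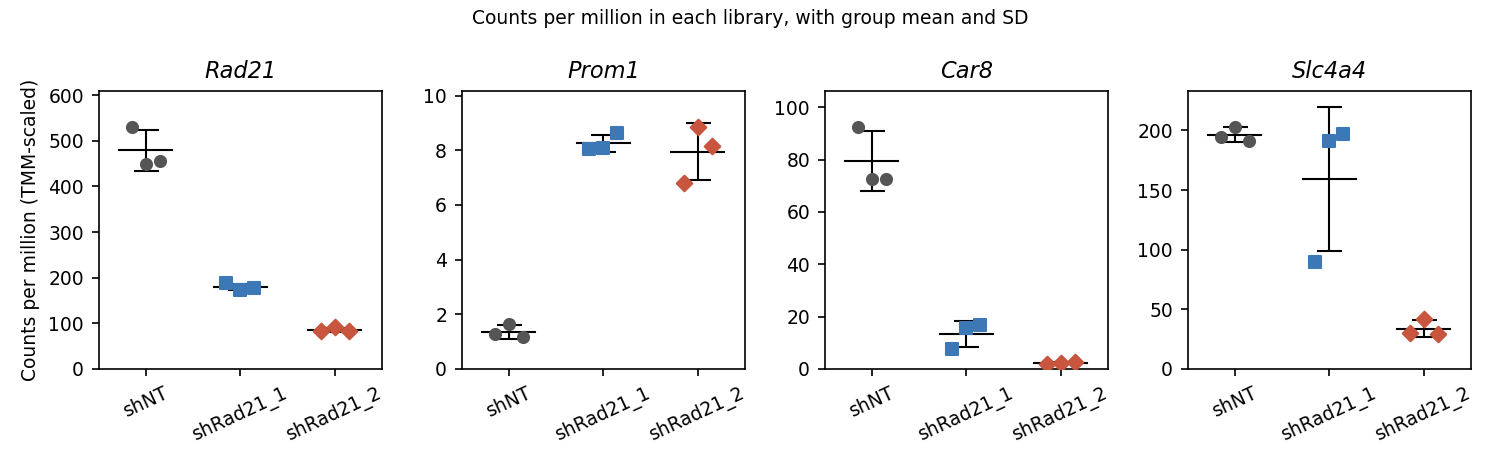
CPM of Rad21, Prom1, Car8 and Slc4a4 in each of the 9 libraries (points), with the mean of each group of 3 and its SD. Rad21 means were 479, 180 and 85.3 CPM in shNT, shRad21_1 and shRad21_2, and Prom1 means were 1.35, 8.25 and 7.94 CPM.

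The groups separated on the first principal component, which held 60.2% of the variance. shNT libraries lay at -39.8, -48.3 and -47.8 and shRad21_2 libraries at 50.8, 55.7 and 58.3. shRad21_1 replicates 2 and 3 lay at -20.3 and -21.2, whereas replicate 1 lay at 12.6, on the side of shRad21_2. That replicate also stood apart in astrocyte markers, whose median log2 level relative to the mean of shNT was -1.34 in it, 0.08 and 0.07 in the other shRad21_1 libraries and -1.95, -2.16 and -2.17 with shRad21_2. Its p53 targets stood at 0.82, against 0.26 and 0.27. Some libraries were closer than others of their group. Chi-square per gene was 3.20 between shNT replicates 2 and 3 and 2.18 between shRad21_1 replicates 2 and 3, and between 23.2 and 70.7 for the other pairs within a group.

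**Figure D2:**
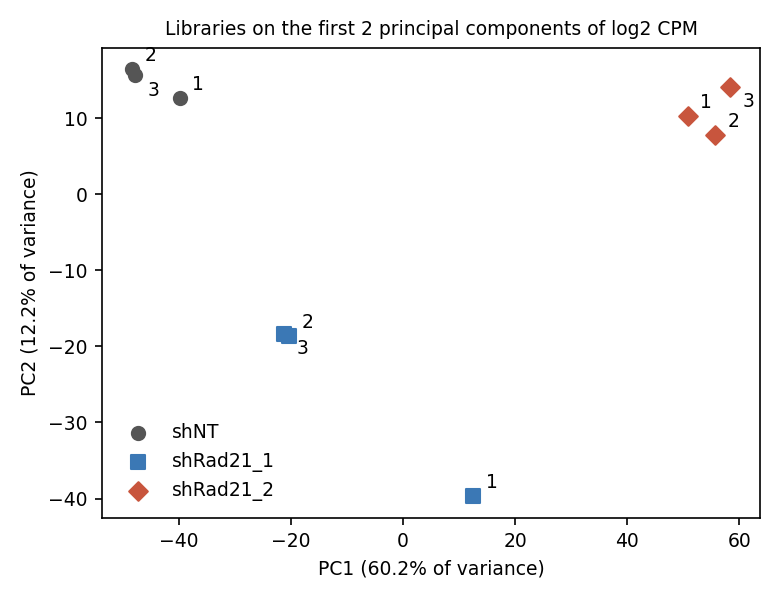
Principal components 1 and 2 of log2 CPM, with the share of variance on each axis; each point is a library and colours mark the 3 groups. shRad21_1 replicate 1 lay at 12.6 on the first component, apart from the 2 other libraries of its group at -20.3 and -21.2.

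The comparison of shRad21_1 with shNT asks which transcripts differ when Rad21 mRNA is lowered with the weaker hairpin. Prom1, which encodes the stem cell surface protein prominin-1, rose from 1.35 ± 0.249 to 8.25 ± 0.319 CPM (log2 fold change 2.61, SE 0.18, edgeR adjusted p = 1.73e-04). Edaradd, an adaptor of the ectodysplasin receptor, rose by 2.99 (SE 0.28) and Plxdc2 by 3.27 (SE 0.38). The polysialyltransferase gene St8sia2 rose by 2.27 (SE 0.25) and the homeobox gene Irx5 by 1.84 (SE 0.17). Among genes that fell, Sulf1, a heparan sulfate endosulfatase, went from 8.56 ± 0.290 to 0.662 ± 0.255 CPM (-3.69, SE 0.34, adjusted p = 4.45e-04). Ankrd34c changed by -3.27 (SE 0.28), Itih5 by -2.87 (SE 0.35) and Lrrc32 by -2.71 (SE 0.32). Car8, a carbonic anhydrase-related gene at 79.4 ± 11.4 CPM in shNT, fell by 2.56 (SE 0.26, adjusted p = 6.34e-04). The rule for naming these genes required all 3 knockdown libraries to lie beyond all 3 shNT libraries. Each of them was called with every library left out in turn.

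Other large values under shRad21_1 depended on single libraries. Calb2, which encodes calretinin, had 4 counts in the 3 shNT libraries together and 349 with shRad21_1, of which 290 were in replicate 1 (ratio 95.6, interval 37.0 to 353). Its log2 fold change was 6.46 (SE 1.26, edgeR adjusted p = 0.0122) and 4.47 without that replicate. Without shNT replicate 1 it was 7.75. The call was lost without shNT replicate 2 (6.28, adjusted p = 0.0622) or replicate 3 (5.85, adjusted p = 0.0585), within a range of 1.60e-05 to 0.0622 over 16 alternatives. Hydin, a gene of motile cilia, had a value of 3.41 (SE 0.77) that was 1.75 without shRad21_1 replicate 1. Its call was lost without any of the shNT libraries (3.52, 3.37 and 3.34). Vgll3, at 2.17 (SE 0.51), was 1.28 without shRad21_1 replicate 1 and was likewise lost without any of the shNT libraries (1.95, 2.27 and 2.34). Syt1, which encodes synaptotagmin 1, rose by 2.65 (SE 0.46, adjusted p = 0.00775), and by 1.71 without shRad21_1 replicate 1. The predicted gene Gm14434 changed by -3.87 (SE 0.81). Its call was lost without shNT replicate 2 (-3.25) and without shRad21_1 replicate 2 (-3.56) or replicate 3 (-3.77).

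Protocadherins and p53 targets had the most members called under shRad21_1. Of 47 clustered protocadherins tested, 11 rose and 6 fell; adjusted over the list alone, 16 rose and 11 fell. Of 27 p53 targets, 9 rose and 3 fell (16 and 3 adjusted over the list alone). Pidd1 rose from 17.0 ± 0.619 to 31.8 ± 5.05 CPM (0.90, SE 0.12, edgeR adjusted p = 0.00256) and Plk2 by 0.90 (SE 0.15). The members that fell were Btg2 (-0.65), Sesn1 (-0.58) and Plk3 (-0.59). The p53 list passed camera (adjusted p = 4.48e-04), with an adjusted p = 0.974 with an estimated correlation. The numbers of p53 targets that rose and fell were 3 and 4 without shNT replicate 1 and 2 and 1 without shNT replicate 2 or 3. The 6 fallen protocadherins numbered 3, 2 and 3 without shNT replicate 2, shNT replicate 3 and shRad21_1 replicate 2, and the 11 risen ones 7 without shNT replicate 3. With close pairs of libraries summed, an alternative chosen after seeing the data, 2 p53 targets and 5 protocadherins rose and 0 of either fell. Btg2 was no longer called without shNT replicate 2 (-0.66) or 3 (-0.65). Plk3, chosen after its values were seen, kept its call in 1 of 6 such fits and lost it without shNT replicate 2 or 3 or any shRad21_1 library, with values from -0.70 to -0.44.

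Single members stood out in other lists under shRad21_1. Phf8, a histone demethylase in the PHF2 family, fell from 39.2 ± 1.11 to 17.6 ± 1.59 CPM (-1.15, SE 0.09, edgeR adjusted p = 3.46e-04), and Ifi27 rose from 15.0 ± 0.928 to 35.2 ± 2.18 CPM (1.23, SE 0.11, adjusted p = 3.63e-04). In the PHF2 list of 17, 1 rose and 1 fell, the same counts as adjusted over the list alone. Of 30 interferon-stimulated genes, 2 rose and 1 fell (2 and 2 adjusted over the list alone). Besides Ifi27 these were Usp18 (2.33) and Bst2 (-0.94), both chosen after their values were seen. Of 20 genes of the cohesin list, Stag1 rose by 0.61 (SE 0.08) and Esco1 by 0.54 (SE 0.08), and only Rad21 fell; adjusted over the list alone 2 rose and 3 fell. Of 25 neural stem cell markers, Prom1, Gli3 (0.80) and Hmga2 (1.03, chosen after its values were seen) rose and Ednrb fell (-0.32); adjusted over the list alone 3 rose and 2 fell. Of 19 neuronal markers, Syt1, Dlx1 (0.84) and Dlx2 (1.37, chosen after its values were seen) rose, and Gad1 (-1.07), Gap43 (-0.89) and Mapt (-1.20) fell; adjusted over the list alone 5 rose and 4 fell. Bst2 and Hmga2 lost their calls without any of the shNT libraries or without shRad21_1 replicate 2 or 3. Their values ran from -1.16 to -0.82 and from 0.82 to 1.27. Usp18 and Dlx2 lost theirs without shRad21_1 replicate 2 or 3, Usp18 also without shNT replicate 2 or 3 and Dlx2 without shNT replicate 1 or 2, with values from 1.87 to 3.41 and from 1.19 to 1.60. Ednrb and Mapt lost theirs without any of the shNT libraries or without shRad21_1 replicate 2 or 3, with values from -0.43 to -0.27 and from -1.43 to -0.79 over 16 alternatives. Gap43 lost its call without shNT replicate 2 (-0.88) or 3 (-0.87), and Dlx1 without shNT replicate 3 (0.88). The neuronal members numbered 2 higher and 1 lower without shNT replicate 2 or 3. With close pairs summed, chosen after seeing the data, the cohesin, stem cell and neuronal lists had 0, 1 and 1 members higher, and Rad21 was the 1 lower among the 3 lists.

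G1/S regulators went both ways under shRad21_1, and the other lists of this paragraph had between 0 and 2 members called. Of 21 G1/S regulators, Myc (0.72), Ccne1 (0.35) and E2f3 (0.36) rose and Cdk6 (-1.95), Cdkn2a (-0.70) and Cdkn2c (-0.34) fell; adjusted over the list alone 4 rose and 3 fell. Ccne1, E2f3 and Cdkn2c were chosen after their values were seen. The numbers of G1/S regulators higher and lower were 1 and 2 without shNT replicate 1, 1 and 1 without shNT replicate 2, and 0 and 1 without shNT replicate 3, shRad21_1 replicate 2 or shRad21_1 replicate 3. Cdk6 was called without each library in turn but not in 1 of 16 alternatives, where its adjusted p was 0.0702. The others lost their calls without shRad21_1 replicate 2 or 3 or shNT replicate 3, and further without shNT replicate 1 (Myc, E2f3, Cdkn2c), shNT replicate 2 (all but Myc) and shRad21_1 replicate 1 (E2f3). Values ran from 0.59 to 0.87 for Myc and from -0.85 to -0.56 for Cdkn2a over 16 alternatives, and without each library from 0.31 to 0.39 for Ccne1, 0.35 to 0.37 for E2f3 and -0.38 to -0.28 for Cdkn2c. Of 22 cholesterol genes Sqle (0.36) and Cyp51 (0.25, chosen after its values were seen) rose (1 adjusted over the list alone). Both calls were lost without any of the shNT libraries or without shRad21_1 replicate 2 or 3, and that of Sqle also without replicate 1 (0.23). Their values ran from 0.23 to 0.42 over 16 alternatives and from 0.24 to 0.26 without each library. Pdgfra was the 1 of 12 oligodendrocyte markers that fell (62.3 ± 2.54 to 31.2 ± 10.7 CPM); adjusted over the list alone 1 rose and 3 fell. Its call was lost without any of the shNT libraries (-0.96, -1.01 and -1.02). Hoxa5 was the 1 of 5 Hox genes that rose (0.98), also adjusted over the list alone, and its call was lost without shNT replicate 2 (0.92) or 3 (0.96) or shRad21_1 replicate 2 (0.99). Btg2 was the 1 of 21 immediate early genes that fell, also adjusted over the list alone, and without shRad21_1 replicate 1 the list had 1 higher and 3 lower. edgeR called 0 of 45 DNA replication, 30 mitosis, 26 DNA repair, 13 inflammatory, 20 stress response and 14 astrocyte genes. At an unadjusted p under 0.05 those lists had 4, 2, 5, 4, 4 and 3 genes, the DESeq2 Wald test called 2, 1, 1, 2, 3 and 0, and limma-voom 0 in each. Without shNT replicate 1, 6 stress response genes fell. edgeR also called 0 of 12 condensin genes, 37 histones and 2 microglial markers, with 0 at an unadjusted p and 0 by both other tools. For 7 mesenchymal and 6 endothelial markers the count was 0, with 2 and 1 at an unadjusted p, 2 and 1 by DESeq2 and 0 by limma-voom. In these 11 lists adjustment over the list alone gave 0 as well, except for 1 endothelial marker that fell. Of 77 ribosomal protein genes 0 were called (3 at an unadjusted p, 0 by DESeq2, 0 by limma-voom and 0 adjusted over the list alone), although the list passed camera (median log2 fold change 0.11, adjusted p = 0.0108; adjusted p = 0.974 with an estimated correlation).

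In all, 1331 of 13560 genes differed between shRad21_1 and shNT (9.82%), 568 higher and 763 lower. Of these, 425 changed at least 2-fold, 149 higher and 276 lower. The count was 467 without shNT replicate 2, 460 without shNT replicate 3, 790 without shRad21_1 replicate 2 and 801 without shRad21_1 replicate 3. It was 130 with close pairs summed, chosen after seeing the data.

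The comparison of shRad21_2 with shNT asks the same of the hairpin that left less Rad21 mRNA. Over all 13560 genes tested 43.6% were called, 2861 higher and 3056 lower. Counts within a list are to be read against these shares. Of 14 astrocyte markers 10 fell and 0 rose, the same counts as adjusted over the list alone (median log2 fold change -2.22). The bicarbonate transporter gene Slc4a4 went from 196 ± 6.26 to 33.5 ± 7.23 CPM (-2.55, SE 0.27, edgeR adjusted p = 7.80e-05), and Atp1b2 from 361 ± 23.7 to 33.5 ± 1.01 CPM (-3.43, SE 0.47, adjusted p = 3.44e-04). Aldh1l1 fell by 2.79 (SE 0.24), S100b by 2.55 (SE 0.36). Gfap, the astrocyte intermediate filament, had 4 counts in the 3 shRad21_2 libraries against 1005 in shNT, a ratio of 244 (interval 95.0 to 897). Of 12 oligodendrocyte lineage markers 8 fell and 1 rose, also adjusted over the list alone. Pdgfra went from 62.3 ± 2.54 to 5.2 ± 0.969 CPM (-3.59, SE 0.26, adjusted p = 9.51e-06), Nkx2-2 changed by -2.54 (SE 0.34) and Opalin by -3.08 (SE 0.51), while Olig2 rose by 0.33 (SE 0.07). Both lists passed camera (adjusted p = 3.38e-05 and 0.00790), with an adjusted p = 0.694 with an estimated correlation for each. Slc4a4 and Atp1b2 were also low in shRad21_1 replicate 1, at 89.9 and 48.0 CPM against 191 and 223 in replicate 2 and 197 and 227 in replicate 3. Gfap had a fitted value of -7.69, which was -7.02 without shRad21_2 replicate 1 and -8.96 without replicate 3, and was not called by limma-voom. The value of Opalin was -3.87 without shRad21_2 replicate 1.

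Stem cell and neuronal markers went both ways under shRad21_2. Of 25 neural stem cell markers 8 rose and 9 fell (8 and 11 adjusted over the list alone). Prom1 rose to 7.94 ± 1.05 CPM (2.55, SE 0.18, edgeR adjusted p = 7.16e-06) and Gli3 from 17.4 ± 0.841 to 52.7 ± 9.89 CPM (1.60, SE 0.14). Ednrb fell from 436 ± 15.3 to 151 ± 8.14 CPM (-1.53, SE 0.08, adjusted p = 2.78e-06) and Ptprz1 by 1.94 (SE 0.20). Of 19 neuronal markers 6 rose and 6 fell, also adjusted over the list alone, and 3 rose without shNT replicate 2. Gad1, an enzyme of GABA synthesis, went from 9.77 ± 1.22 to 1.27 ± 0.105 CPM (-2.93, SE 0.16, adjusted p = 2.78e-06). Gap43 fell by 1.72 (SE 0.18) and Mapt by 2.36 (SE 0.35), while Dlx1 rose by 0.61 (SE 0.17).

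Some interferon, inflammatory and immediate early genes were lower under shRad21_2. Of 30 interferon-stimulated genes 10 fell and 0 rose, also adjusted over the list alone (median -0.80). Parp9 went from 9.47 ± 0.162 to 3.19 ± 0.793 CPM (-1.56, SE 0.18, edgeR adjusted p = 1.29e-04), Parp14 changed by -2.02 (SE 0.26) and Trim25 by -1.98 (SE 0.28). The list passed camera (adjusted p = 0.00792; adjusted p = 0.694 with an estimated correlation). Of 21 immediate early genes 7 fell and 2 rose, also adjusted over the list alone. The immediate early and inflammatory lists did not pass camera (adjusted p = 0.0920 and 0.356). The median log2 level of the immediate early genes relative to shNT was -0.38 in shNT replicate 1 and 0.17 and 0.21 in the other shNT libraries. It was -0.57 in shRad21_1 replicate 1, 0.09 and 0.19 in replicates 2 and 3, and -0.88, -0.54 and -0.43 with shRad21_2. Fos went from 123 ± 26.1 to 15.8 ± 1.16 CPM (-2.96, SE 0.69), Fosb changed by -4.40 (SE 0.84) and Ier3 by -2.68 (SE 0.33). The 2 that rose, both chosen after their values were seen, were Etv4 (0.24) and Klf2 (0.79). Fos had a group SD of 62.5 CPM with shRad21_1, around a mean of 81.4. Of 13 inflammatory genes 6 fell, among them Vcam1 (-1.20), Lif (-1.12) and Ccl2 (-0.88), and Nfkb1 rose (0.81), also adjusted over the list alone. The 7 immediate early genes became 4 without shRad21_2 replicate 2 or 3, and the 6 inflammatory genes 3 without shNT replicate 3 or shRad21_2 replicate 3. Etv4 and Klf2 lost their calls without shNT replicate 1 or 2 or shRad21_2 replicate 3, and Etv4 also without shRad21_2 replicate 1 (values from 0.19 to 0.31 and from 0.61 to 0.95).

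Ribosomal protein genes rose by small amounts under shRad21_2. Of 77 tested, 57 rose and 0 fell (62 and 0 adjusted over the list alone), with a median log2 fold change of 0.40. Rpl35 went from 487 ± 10.4 to 733 ± 115 CPM (0.59, SE 0.10, edgeR adjusted p = 0.00153) and Rpl15 rose by 0.49 (SE 0.08, adjusted p = 0.00105). The list passed camera (adjusted p = 1.05e-09; adjusted p = 0.694 with an estimated correlation). With close pairs summed, chosen after seeing the data, 36 rose. Of 37 histone genes 12 rose and 0 fell (9 and 0 adjusted over the list alone; camera adjusted p = 0.0369; adjusted p = 0.694 with an estimated correlation). Hist1h2ag stood at 1.07 ± 0.584 CPM with shRad21_2, and the 12 became 2, 3 and 1 without shNT replicate 2, shNT replicate 3 and shRad21_2 replicate 1. The median log2 fold change of the list was 0.98, and 0.43 without shRad21_2 replicate 1, the library with 0.483% of its counts on Rn45s. Relative to shNT the median level was 0.63, 0.20 and 0.26 in the shRad21_2 libraries, 0.16, -0.14 and -0.07 in shNT, and 0.19, -0.06 and -0.14 with shRad21_1.

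Cell cycle and chromosome genes were in part higher under shRad21_2, where 2861 of all 13560 genes tested were higher. Rrm2, a subunit of ribonucleotide reductase, rose from 351 ± 27.6 to 555 ± 36.0 CPM (0.66, SE 0.08, edgeR adjusted p = 1.65e-04). It was among 14 of 45 DNA replication genes that rose, with Mcm10 (0.41), while Rpa1 fell (-0.24); adjusted over the list alone 10 rose and 0 fell. Of 30 mitosis genes 11 rose, among them Ube2c (0.65, SE 0.15), and 0 fell (10 and 0 adjusted over the list alone). Of 26 DNA repair genes 6 rose, among them Parp1, Tipin (0.45 each) and Exo1 (0.48), and 0 fell, also adjusted over the list alone. The share of DNA repair genes that rose was near that over all genes. Of 20 cohesin genes 9 rose and 2 fell (10 and 2 adjusted over the list alone). Stag1 went from 106 ± 6.49 to 251 ± 20.9 CPM (1.25, SE 0.09, adjusted p = 7.05e-06), and Rad21 and Hdac8 (-0.47) fell. Of 12 condensin genes 4 rose, Smc4 (0.42), Smc6 (0.31), Ncaph (0.34) and Ncapd2 (0.34), and 0 fell, also adjusted over the list alone. DNA replication and mitosis passed camera (adjusted p = 0.00792 and 0.00577), both with an adjusted p = 0.694 with an estimated correlation. The 11 mitosis genes became 22 without shNT replicate 1, 2 without shNT replicate 2 or 3, 4 without shRad21_2 replicate 1 and 7 without shRad21_2 replicate 3. The 14 replication genes became 5 without shNT replicate 2 or 3 and 6 without shRad21_2 replicate 3. The 9 cohesin genes became 5 without shNT replicate 2 and the 4 condensin genes 2 without shNT replicate 2 or 3. Rpa1 kept its call without shRad21_2 replicate 3 and lost it without each of the other libraries of the 2 groups, with values from -0.31 to -0.18 over 16 alternatives. Ncaph lost its call without shNT replicate 2 or 3 (0.31 each). Ncapd2 lost its own without shNT replicate 2 (0.27) or 3 (0.28) or shRad21_2 replicate 1 (0.27). The median of the mitosis genes was 0.27 in shNT replicate 1, -0.15 and -0.14 in the other shNT libraries, and 0.41, 0.28 and 0.33 with shRad21_2.

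**Figure D3:**
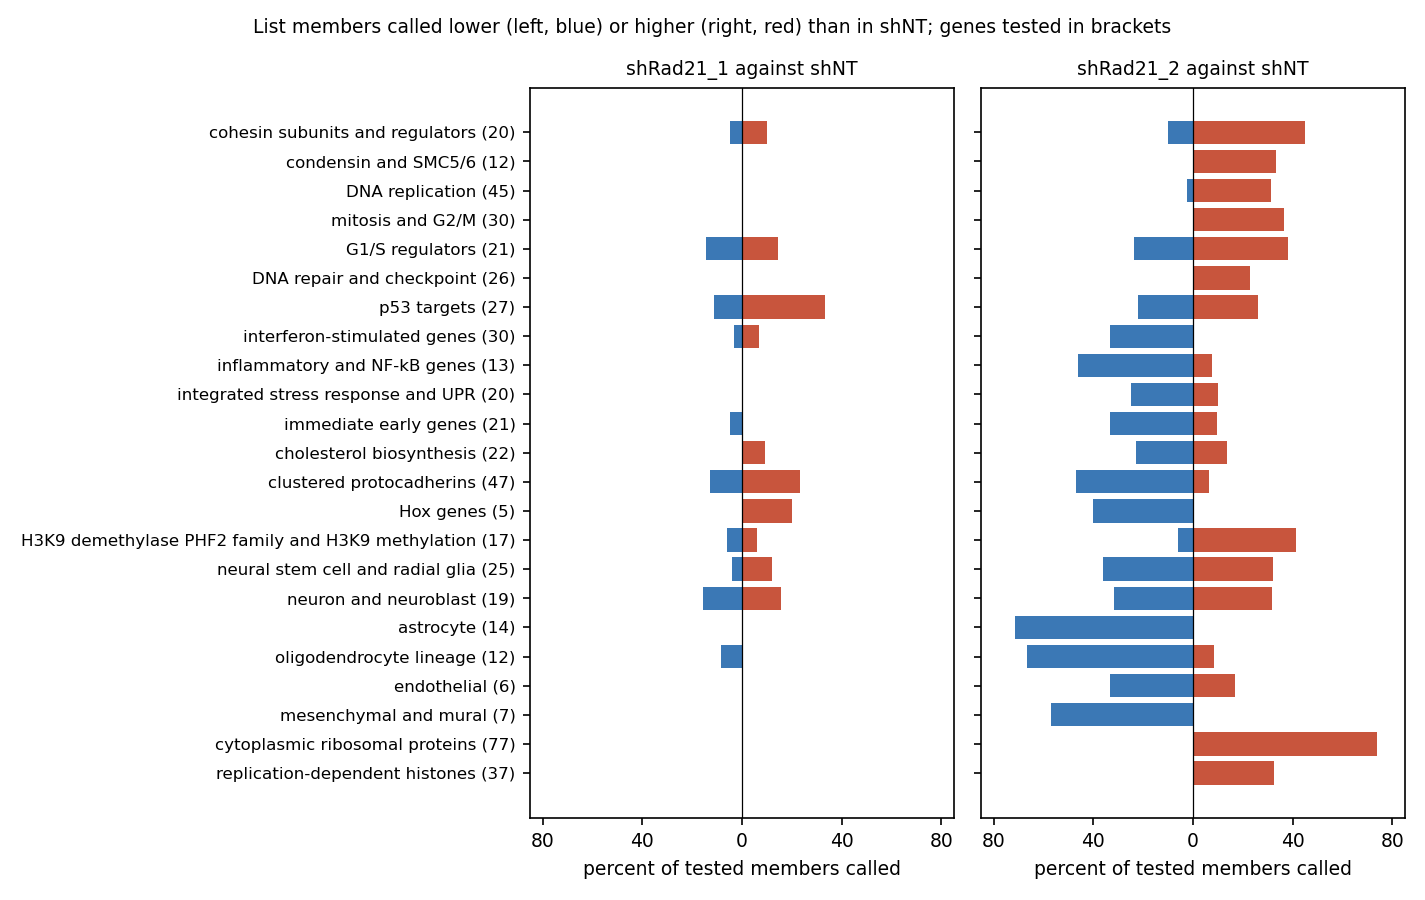
Percent of the tested members of each gene list called higher or lower against shNT under each hairpin. Of 14 astrocyte markers 0 were called under shRad21_1 and 10 were lower under shRad21_2, and of 77 ribosomal protein genes 0 and 57 were higher.

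G1/S regulators and p53 targets split under shRad21_2. Over all genes tested 43.6% were called, a share that the cholesterol and stress response lists did not reach. Of 21 G1/S regulators 8 rose, among them Cdkn1c (2.01, SE 0.20) and Myc (1.04, SE 0.16). Cdk6 (-4.51), Cdkn2a (-1.07), Cdkn2b (-1.34), Ccnd2 (-0.27) and Cdkn2c (-0.25) fell; adjusted over the list alone 9 rose and 6 fell. Cdkn2b, Ccnd2 and Cdkn2c were chosen after their values were seen. Of 27 p53 targets 7 rose, among them Plk2 (0.97) and Pidd1 (0.75), and 6 fell, among them Btg2 (-1.32) and Sesn1 (-0.46); adjusted over the list alone 8 rose and 6 fell. In the cholesterol list of 22, 3 rose, among them Sqle (0.35), and Hmgcs1 (-0.89), Lss (-0.65), Msmo1 (-0.53), Sc5d (-0.29) and Cyp51 (-0.28) fell; adjusted over the list alone 2 rose and 5 fell. In the stress response list of 20, Psat1 (0.79) and Phgdh (0.46) of serine synthesis rose, and Dnajb9 (-0.72), Ddit3 (-0.60), Pdia4 (-0.44), Calr (-0.37) and Xbp1 (-0.31) fell; adjusted over the list alone 2 rose and 3 fell. Lss, Sc5d, Cyp51, Phgdh, Ddit3, Calr and Xbp1 were chosen after their values were seen. Cdk6 was at -5.32 without shRad21_2 replicate 1. The 5 fallen G1/S regulators became 3 without shNT replicate 3 or shRad21_2 replicate 3, where Ccnd2 and Cdkn2c were no longer called (values from -0.33 to -0.22 and from -0.31 to -0.20). Ccnd2 lost its call also without shNT replicate 2 or shRad21_2 replicate 1, and Cdkn2c also without shNT replicate 1 or shRad21_2 replicate 2. The 3 risen cholesterol genes became 1 without shNT replicate 2 or 3, where Sqle was among those lost (0.33 and 0.34). Sc5d lost its call without shNT replicate 2 or 3 or shRad21_2 replicate 3 (values from -0.35 to -0.26). The 5 fallen stress genes became 8 without shNT replicate 1 and 3 without shNT replicate 2 or 3 or shRad21_2 replicate 1 or 2, where Ddit3 and Xbp1 were lost. Xbp1 was lost also without shNT replicate 1, and the values of Ddit3 and Xbp1 ran from -0.80 to -0.48 and from -0.43 to -0.20. The median level of the stress list was -0.33 in shNT replicate 1 and 0.17 in each other shNT library, against -0.40, -0.17 and -0.01 with shRad21_2.

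Of 17 genes in the PHF2 and H3K9 methylation list, 7 rose under shRad21_2, among them Phf2, Ehmt1 (0.38) and Setdb1 (0.26), and Kdm4c fell (-0.26, chosen after its values were seen), also adjusted over the list alone. The 7 became 4 without shNT replicate 2 or 3, where Setdb1 (0.23 and 0.24) was lost, and Kdm4c was lost without shNT replicate 3, with values from -0.27 to -0.23. Of 5 Hox genes 2 fell, among them Hoxa5 (-1.45, SE 0.24), also adjusted over the list alone. Markers of other cell types were sparse. P2ry12 fell (-2.37) and was 1 of 2 microglial markers tested. Of 6 endothelial markers Eng rose (1.33), while Kdr (-1.56) and Flt1 fell. Flt1 had 38 counts in shNT and 0 with shRad21_2, and the lower limit of the exact interval on its fall was 9.52-fold. With 3 counts over the whole group taken as a floor, the fall was 12.3-fold. Of 7 mesenchymal markers Acta2 (-4.35), Fn1 (-1.22), Foxc1 (-0.36) and Pdgfrb fell, the last with 38 counts in shNT and 7 with shRad21_2 (ratio 5.27, interval 2.33 to 14.0). In these last 3 lists adjustment over the list alone gave the same counts. Pdgfrb lost its call without any of the shNT or shRad21_2 libraries but shNT replicate 3, and its adjusted p ran from 0.0242 to 0.0974 over 14 alternatives.

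In all, 5917 genes differed between shRad21_2 and shNT (43.6%), 2861 higher and 3056 lower. Of these, 1754 changed at least 2-fold, 365 higher and 1389 lower. With library totals only, 2167 genes were higher and 3541 lower. The largest rises were those of Calb2 (4 counts in shNT and 382 with shRad21_2, ratio 98.4, interval 38.1 to 363), Hydin (4.93, SE 0.79), Ly6e (3.96, SE 0.36), Col28a1 (3.72, SE 0.72) and Prrt4 (3.08, SE 0.27). Each was called with every library left out in turn. Calb2 had a fitted value of 6.52, which was 7.81 without shNT replicate 1 and 5.92 without shNT replicate 3. The largest falls were near the floor. Ankrd34c had 1 count with shRad21_2 against 1652 (ratio 1604, interval 287 to 63394), Nebl had 7 against 2342 (ratio 325, interval 157 to 809) and Scg2 had 6 against 1481 (ratio 240, interval 110 to 654). Their fitted values of -10.12, -8.18 and -7.68 were -12.04, -8.85 and -9.52 without shRad21_2 replicate 2. Col6a2, of collagen VI, had a value of -7.31 (SE 1.60), and it and Scg2 were not called by limma-voom.

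Both hairpins changed 1079 genes in the same direction, 438 up and 641 down. Independent calls of the same numbers would give 120 and 172. Besides the genes given for shRad21_1, those with the largest smaller rise were Ly6e (2.19 under shRad21_1 and 3.96 under shRad21_2), Prrt4 (1.75 and 3.08) and Zfp711 (1.72 and 1.74). Those with the largest smaller fall were Gpr37l1 (-2.23 and -6.03), the Wnt ligand gene Wnt4 (-2.18 and -5.13), Car13 (-2.18 and -2.40), As3mt (-2.13 and -2.19), Wnk4 (-2.09 and -4.31), Sez6 (-2.05 and -3.36) and Csdc2 (-1.99 and -3.02). Prom1, Irx5, Car13 and As3mt moved by similar amounts under both hairpins, with differences of -0.06, -0.03, -0.22 and -0.07 that did not pass the test. Car8 and Sulf1 fell further under shRad21_2, with differences of -2.52 (SE 0.28, edgeR adjusted p = 2.98e-04) and -2.24 (SE 0.45, adjusted p = 0.00667). Under shRad21_2 Sulf1 was at -5.93 (-6.82 without shRad21_2 replicate 1) and Wnt4 at -6.03 without that library. The call of Wnk4 under shRad21_1 was lost without shNT replicate 2 (adjusted p = 0.0557) or 3 (adjusted p = 0.0573), within a range of 7.85e-06 to 0.0934 over 16 alternatives. The shared genes were 81.1% of those changed by shRad21_1, and 16 genes changed in opposite directions. Fold changes correlated across genes, which are not independent replicates, at Pearson r = 0.646 and Spearman rho = 0.652. Both comparisons share the shNT libraries. In 20 simulations of unchanged groups with shared controls r was 0.495 on average, between 0.470 and 0.527. The covariance was 0.0330 against 0.311 observed. With no gene changed, only 0.1 genes on average were called under shRad21_1, so the 0 called under both was fixed in advance. The simulated libraries were independent draws, unlike the close pairs of libraries here. These values are therefore no bound on the part of r or covariance that shared controls give. The count of 1079 was 387 without shNT replicate 2, 381 without shNT replicate 3, 656 and 668 without shRad21_1 replicates 2 and 3, and 114 with close pairs summed, chosen after seeing the data.

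**Figure D4:**
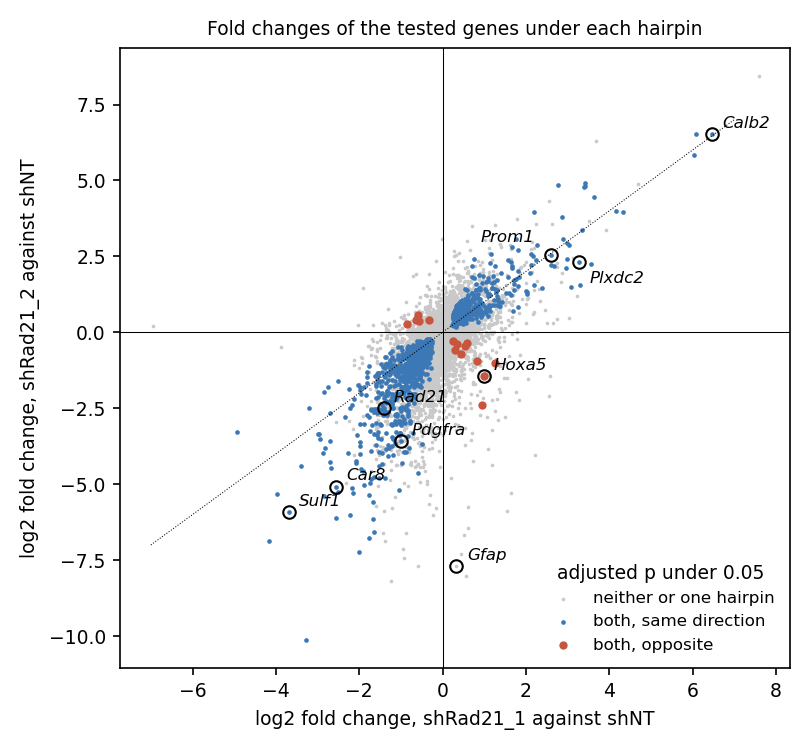
Log2 fold change against shNT under shRad21_2 (y axis) and shRad21_1 (x axis) for each of the 13560 genes tested, with named genes outlined in black. Sulf1 lies at -3.69 and -5.93 and Prom1 at 2.61 and 2.55; r across genes was 0.646.

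The comparison of shRad21_2 with shRad21_1 tests directly where the hairpins differed. Car12, a carbonic anhydrase, stood at 3.30 ± 0.152 CPM in shNT, 3.29 ± 0.971 with shRad21_1 and 27.7 ± 1.84 with shRad21_2 (difference 3.08, SE 0.19, edgeR adjusted p = 1.76e-05). Afap1l2 (2.42, SE 0.21), the junctophilin gene Jph4 (2.25, SE 0.29), Fam19a4 (2.54, SE 0.41) and Ly6e (1.77, SE 0.31) were higher with shRad21_2. So were Gm14434 (3.39), Gm4724 (3.37) and the pseudogene Atp6v0c-ps2 (2.56). Phf8 was higher with shRad21_2 by 1.03 (SE 0.09, adjusted p = 1.05e-04), and Ifi27 lower by -1.20 (SE 0.11, adjusted p = 9.34e-05). Hoxa5 rose under shRad21_1, fell under shRad21_2 and differed by -2.44 (SE 0.24, adjusted p = 1.51e-04). The lowest genes relative to shRad21_1 were Gfap (4 counts against 1123, ratio 299, interval 116 to 1098), Scg2 (ratio 152, interval 69.4 to 414), S100a6 (3 counts against 444, ratio 157, interval 53.5 to 767), Nebl (ratio 137, interval 66.2 to 342) and Ankrd34c (1 count against 154, ratio 164, interval 29.0 to 6514). Col6a2 (-7.75, SE 1.60), Col6a1 (-6.37, SE 1.26) and Acta2 (-5.53, SE 0.54) were lower as well. Several were uneven within shRad21_1, where replicate 1 was low and the pooled counts came largely from replicates 2 and 3. In replicates 1, 2 and 3 the counts were 7, 549 and 567 for Gfap, 25, 400 and 430 for Scg2, 7, 221 and 216 for S100a6 and 91, 391 and 419 for Nebl. Levels were 6.55, 109 and 114 CPM for Col6a1 and 1.60, 36.1 and 37.5 CPM for Col6a2. In shNT, Col6a1 stood at 5.77, 73.2 and 71.2 CPM, Col6a2 at 1.68, 27.4 and 26.3 CPM and Scg2 at 2.78, 15.7 and 15.8 CPM. Syt1 was lower by -2.33 (SE 0.45, adjusted p = 0.00561), but its rise of 2.65 under shRad21_1 was 1.71 without shRad21_1 replicate 1.

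Some of these calls rested on single libraries. Gm14434 lost its call without shRad21_1 replicate 2 (3.08) or 3 (3.29) and was at 2.77 without shRad21_2 replicate 2. Gm4724 lost its call without shRad21_1 replicate 2 (3.27) or 3 (3.16) or shRad21_2 replicate 1 (2.85). Atp6v0c-ps2 lost its call without shRad21_1 replicate 2 (2.54) or shRad21_2 replicate 1 (2.03) or 3 (2.47). The fitted values of Scg2 (-7.08), S100a6 (-7.06), Nebl (-6.95) and Ankrd34c (-6.84) were -8.93, -7.98, -7.62 and -8.77 without shRad21_2 replicate 2. That of Gfap (-8.02) was -7.35 without shRad21_2 replicate 1 and -9.30 without replicate 3. limma-voom did not call Gfap, Scg2, S100a6, Col6a1 or Col6a2.

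Between the hairpins, 10 of 14 astrocyte markers (11 adjusted over the list alone; median -2.03) and 7 of 12 oligodendrocyte markers (8) were lower with shRad21_2, as were 16 of 30 interferon-stimulated genes (19; median -1.05) and 24 of 47 protocadherins (25). These lists passed camera at adjusted p = 5.34e-07, 0.00119, 3.12e-06 and 4.41e-07. They had an adjusted p = 0.395 with an estimated correlation for the astrocyte, oligodendrocyte and protocadherin lists and adjusted p = 0.447 for the interferon list. The interferon count was 10 without shRad21_2 replicate 3. In the same lists Bst2 (1.43) and Bcas1 (0.34), an interferon-stimulated gene and an oligodendrocyte marker chosen after their values were seen, were higher with shRad21_2. The call of Bcas1 was lost without shRad21_1 replicate 2 or 3, with values from 0.28 to 0.41. Ribosomal protein genes were higher in 34 of 77 cases (43 adjusted over the list alone), mitosis genes in 11 of 30 (14), DNA replication genes in 18 of 45 (21), DNA repair genes in 9 of 26 (9) and condensin genes in 5 of 12 (6). Those 34 became 9, 8 and 20 without shRad21_1 replicate 2, shRad21_1 replicate 3 and shRad21_2 replicate 3, and 0 with close pairs summed, chosen after seeing the data. The 11 mitosis genes became 27 without shRad21_1 replicate 1, 3 without shRad21_1 replicate 2 or 3, 5 without shRad21_2 replicate 1 and 6 without shRad21_2 replicate 3. The 18 replication genes became 11 without shRad21_1 replicate 2 or 3 and 8 without shRad21_2 replicate 3. The 9 repair genes became 5 without shRad21_1 replicate 2 or 3, and the 5 condensin genes between 1 and 3 without shRad21_1 replicate 2 or 3 or any of the shRad21_2 libraries. In all, 3563 genes differed (26.3%), 1608 higher and 1955 lower with shRad21_2 (1095 and 2310 with library totals only). The count was 2045 and 2055 without shRad21_1 replicates 2 and 3, 2233 with these 2 groups alone in the fit and 1270 with close pairs summed.

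The mean of both hairpins against shNT asks what changed on average over the 2 hairpins. A change under shRad21_2 alone can be enough for a call, so these calls are not changes shared by both hairpins. It called 4528 genes (33.4%), 2074 higher and 2454 lower, of which 1140 changed at least 2-fold. With library totals only, 1650 were higher and 2793 lower. Rad21 was at -1.95 (SE 0.07, edgeR adjusted p = 4.97e-07), Prom1 at 2.58 (SE 0.16, adjusted p = 1.11e-05) and Sulf1 at -4.81 (SE 0.29, adjusted p = 7.53e-06). Astrocyte markers fell in 9 of 14 cases (10 lower and 1 higher adjusted over the list alone), oligodendrocyte markers in 6 of 12 with 1 higher (6 and 1), and ribosomal protein genes rose in 40 of 77 (45). Under shRad21_1 alone, edgeR called 0 of the astrocyte and 0 of the ribosomal protein genes, and 1 oligodendrocyte marker fell. These lists passed camera at adjusted p = 5.28e-04, 0.0284 and 1.99e-07, with an adjusted p = 0.857 with an estimated correlation for each. The 40 became 9, 5 and 8 without shNT replicates 1, 2 and 3, and 0 with close pairs summed, chosen after seeing the data. The gene count was 2568 and 2541 without shNT replicates 2 and 3, and 2033 with close pairs summed.

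The clusters of protocadherin genes, cell surface adhesion proteins of neural cells, moved apart. Under shRad21_1, 10 of 21 beta genes rose and 0 fell (median 0.56), while 6 of 22 gamma genes fell and 0 rose (median -0.70). Pcdhb5 went from 26.2 ± 0.192 to 47.4 ± 0.780 CPM (0.85, SE 0.07, edgeR adjusted p = 3.46e-04) and Pcdhb3 rose by 1.34 (SE 0.15). Pcdhga10 fell by 1.55 (SE 0.22) and Pcdhga7 by 1.14 (SE 0.21). Under shRad21_2, 16 gamma genes fell and 0 rose (median -1.02), with Pcdhga10 at -1.95 (SE 0.22) and Pcdhga7 at -1.61 (SE 0.22). Of the beta genes 2 rose, Pcdhb5 (0.34, SE 0.07) and Pcdhb3 (0.87, SE 0.15), and Pcdhb11 (-0.59), Pcdhb18 (-0.56), Pcdhb12 (-0.72) and Pcdhb21 (-0.76) fell. Of 4 alpha genes, Pcdha9 rose under shRad21_1 (2.03) and shRad21_2 (1.26), and Pcdha12 (-3.11, 68 counts in shNT and 7 with shRad21_2) and Pcdhac2 (-1.33) fell under shRad21_2. The alpha genes and the 4 fallen beta genes were chosen after their values were seen. Over all 47, 3 rose and 22 fell under shRad21_2 (3 and 25 adjusted over the list alone; camera adjusted p = 0.00895; adjusted p = 0.694 with an estimated correlation). Between the hairpins 15 beta and 8 gamma genes were lower with shRad21_2 and 0 were higher. Pcdhb5 differed by -0.51 (SE 0.07, adjusted p = 0.00103). The annotated spans of Pcdhga7 (37714764 to 37841873) and Pcdhga10 (37746993 to 37841873) overlap and have the same end. Counts of gamma genes may therefore not be separate measurements. The numbers of gamma genes that fell are not numbers of independent changes. Spans of the alpha genes are not given here, so the same may hold for them.

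Without each library in turn the 10 risen beta genes under shRad21_1 stayed within 1.5 times that number, and the 6 fallen gamma genes were 3 without shNT replicate 2 or shRad21_1 replicate 2 and 2 without shNT replicate 3. With close pairs summed, chosen after seeing the data, these counts were 5 and 0. The 4 fallen beta genes under shRad21_2 were 2 without shNT replicate 2 or 3 or shRad21_2 replicate 1 or 3. Those lost were Pcdhb12 and Pcdhb21 (-0.89 to -0.54 and -1.16 to -0.56), the latter also without shNT replicate 1. The 15 beta genes between the hairpins were 9 without shRad21_1 replicate 2 or 3 and 8 without shRad21_2 replicate 3. Under shRad21_2 Pcdha9 was not called without shNT replicate 1 or 3 or shRad21_2 replicate 1 or 2 (1.02 to 1.56), and Pcdhac2 was not called whichever library of the 2 groups was left out (-1.41 to -1.20). Under shRad21_1 Pcdha9 was not called without shNT replicate 3 (1.88 to 2.25).

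**Figure D5:**
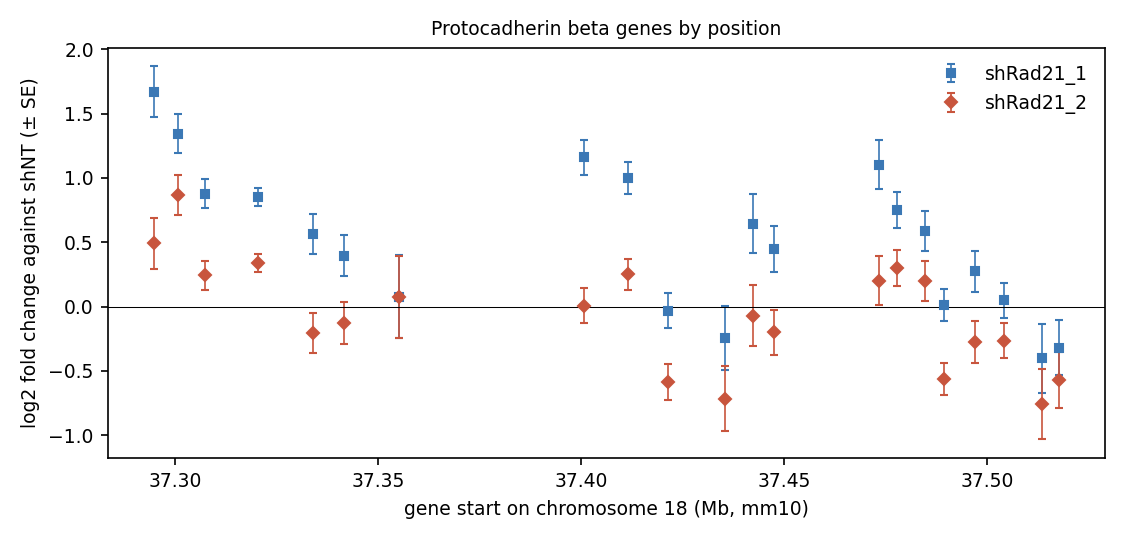
Log2 fold change against shNT with its SE for the 21 protocadherin beta genes tested, by start on chromosome 18, under each hairpin. Under shRad21_1, 10 were called higher and 0 lower, with Pcdhb5 at 0.85 and Pcdhb3 at 1.34.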

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

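In this part, the tests chosen only after the result was seen were those of Rad21 mRNA in shRad21_1 replicate 1, of a culture difference shared with shNT replicate 1, of the gene counts without shRad21_1 replicate 1, and of the genes called under both hairpins in 1 direction or in opposite directions.

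A test of the difference between the 2 hairpins (edgeR, 3 libraries against 3) picked out each result in this paragraph. It called 3563 genes, which were 2045 and 2055 without shRad21_1 replicates 2 and 3, and 78 of the 132 genes named by rule. The rule took 8 higher and 8 lower genes from this same test, and most others for calls or small p against shNT. The 78 are therefore no evidence of enrichment. Rad21 was lower with shRad21_2 by a log2 difference of -1.08. Higher with shRad21_2 were Car12 (3.08), Fam19a4 (2.54), Afap1l2 (2.42), Jph4 (2.25), Ly6e (1.77) and Phf8 (1.03). Gm14434 (3.39; not called without shRad21_1 replicate 2, 3.08, or 3, 3.29; 2.77 without shRad21_2 replicate 2) was higher too. So were Gm4724 (3.37; not called without shRad21_1 replicate 2, 3.27, or 3, 3.16, or shRad21_2 replicate 1, 2.85) and Atp6v0c-ps2 (2.56; not called without shRad21_1 replicate 2, 2.54, or shRad21_2 replicate 1, 2.03, or 3, 2.47). Lower were Col6a2 (-7.75), Col6a1 (-6.37), Acta2 (-5.53), Hoxa5 (-2.44) and Ifi27 (-1.20). Gfap (-8.02), Scg2 (-7.08), S100a6 (-7.06), Nebl (-6.95) and Ankrd34c (-6.84) had between 1 and 7 counts in shRad21_2, so their fitted values are no bound on the change. Those values were -7.35 and -9.30 for Gfap without shRad21_2 replicates 1 and 3, and -8.93, -7.98, -7.62 and -8.77 for the 4 others without shRad21_2 replicate 2. Of 21 protocadherin beta genes, 15 were lower with shRad21_2 (9 without shRad21_1 replicate 2 or 3, 8 without shRad21_2 replicate 3).

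More genes changed against shNT under shRad21_2 (5917) than under shRad21_1 (1331), a ratio of 4.45. The counts were 4263 and 467 without shNT replicate 2 and 4298 and 460 without shNT replicate 3. With close pairs summed, chosen after seeing the data, they were 3707 and 130. The ratio was larger in each of these fits and so depends on single libraries. Library depth is argued against by a ratio of 4.37 with every library thinned to 34780003 counts (5820 and 1333), and the divergent shRad21_1 replicate 1 as the whole cause by a ratio of 4.29 without it. Control libraries unlike the shRad21_2 cultures cannot be told apart from an effect of the hairpin: against shNT replicate 1, 2 or 3 alone, with the spread taken from the other groups, 1747, 2336 and 2267 genes were called under shRad21_2 and 25, 40 and 13 under shRad21_1; the ratio of 0.771 to the lower of the other 2 met the bound of 0.75 set beforehand, but by a margin too small for a single control library (0.748 of the higher), and a difference of the shRad21_2 cultures would enter the 3563 genes between the hairpins as well. Less Rad21 cannot be told apart from any other stronger effect of that hairpin either: 96.0% of the genes called under both hairpins in 1 direction that also differed between them moved more under shRad21_2, which both would give. For the 16 genes called in opposite directions (3 without shNT replicate 2 or 3, 7 and 5 without shRad21_1 replicates 2 and 3, 72 without shRad21_1 replicate 1, 14 of them among the 16, 24 and 25 without shRad21_2 replicates 1 and 2, 0 with close pairs summed), less Rad21 and another difference between the hairpins cannot be told apart, since their number follows single libraries; hairpin sequences were not used here.

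shRad21_1 replicate 1 lay apart from replicates 2 and 3, with 560 genes 2-fold apart, 225 of them higher. Less Rad21 mRNA in that library is argued against by a level 1.06 times the mean of the other 2. A mixture with shRad21_2 cells is argued against because the median share of 56.5% over 739 genes would give 125 CPM of Rad21 against 187 observed (SD of the other 2 libraries 3.18). A culture difference shared with shNT replicate 1 as the whole cause is argued against by a median move in shNT replicate 1 of 0.142 of that in shRad21_1 replicate 1, although 69.5% of those genes had the same sign and 71 genes were 2-fold apart in shNT replicate 1. The genes were chosen for their move in shRad21_1 replicate 1, which lowers that ratio. Deviations of the 2 libraries from their group means correlated at 0.287 across genes, so a shared difference as part of the cause stays open. Other differences in culture or handling stay open and were not tested, and the design names no biological difference between libraries of a group.

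Ribosomal protein and histone genes were higher under shRad21_2, with median log2 fold changes of 0.40 and 0.98, the latter 0.43 without shRad21_2 replicate 1. The scaling of the libraries as the whole cause is argued against by medians of 0.33 and 0.91 with library totals only, 0.814 of the first value. Transcript length bias and a change in the cells cannot be told apart for the ribosomal protein genes: 102 genes matched on length and level moved by 0.20 at the median (SD 0.49), 0.496 of the ribosomal value, and were themselves longer (1616.5 against 1106 bp). Across the other coding genes, which are not independent replicates, transcript length and change had a rank correlation of -0.011. The knockdown as the source of the rise stays open, and no test of the histone genes by length was run. Histone calls fell from 12 to 1 without shRad21_2 replicate 1, the library with 0.483% of its counts on Rn45s. A cause in that library was not tested.

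Other splits of the libraries into groups of 3 were tested for each count. For single comparisons the 10 splits are too few for a share under 0.05. The real split gave 1331 genes for shRad21_1, 5917 for shRad21_2 and 3563 between the hairpins, and the highest other split gave 3, 0 and 0, so that 1 of 10 splits gave as many each time. For gene lists the real values were 2, 8 and 16 and the highest others 11, 16 and 14, with 10, 6 and 1 of 10 splits as large. For the mean of both hairpins, 100 of 840 splits were drawn. As many genes as its 4528 came from 1 of 100 splits (highest other 4338). As many as the 1079 changed by both hairpins in 1 direction came from 3 of 100 (highest other 2376). These shares measure chance only if libraries can be exchanged, and libraries of a group may not be separate cultures. Chance is therefore not excluded for either count. It cannot be excluded for the 3 lists of the mean either (96 of 100, highest other 18). The other split with 4338 genes set the shRad21_2 libraries against the rest. The splits with 18 lists called 0 genes, and camera with an estimated correlation passed 0 lists in the real split; why other splits pass more lists was not tested.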

How the results depend on the processing

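The tests with close pairs of libraries summed, and without the first libraries of shNT and shRad21_1, were chosen only after the data were seen. In no setting did a gene called in a comparison change direction, and Rad21 stayed called in all, from -1.33 to -1.46 under shRad21_1, -2.41 to -2.56 under shRad21_2 and -1.04 to -1.13 between the hairpins. In the order shRad21_1, shRad21_2, between the hairpins, mean of both and both in 1 direction, the gene counts were 1331, 5917, 3563, 4528 and 1079. Requiring at least 2-fold gave 425, 1754, 961, 1140 and 311, by its own construction. Close pairs summed, with 2 fewer libraries, gave 130, 3707, 1270, 2033 and 114. Each library left out gave ranges of 460 to 1599, 4263 to 5610, 2045 to 4486, 2541 to 4940 and 381 to 1232. The DESeq2 Wald test gave 2002 for shRad21_1 and 1571 in both. On the simulated data for shRad21_1 it recovered 67.2% of 1.5-fold changes and called 33 unchanged genes, against 47.8% and 11 with edgeR. With 2 groups in the fit, 2233 genes were called between the hairpins. The cause of either difference in the real data was not tested. A block for replicate number gave 1436, 6066, 3643, 4717 and 1167, limma-voom 1449, 5908, 3340, 4609 and 1196, and library totals only 1338, 5708, 3405, 4443 and 1069, with a median shift over all genes of -0.06 under shRad21_2. DESeq2 size factors, no filter, at least 1 CPM in 3 libraries and removal of the 2 first libraries kept every gene count within 1.5 times. Lists past camera in the 4 comparisons (2, 8, 16 and 3) were 0, 0, 0 and 0 with an estimated correlation (0, 0, 2 and 0 at an unadjusted p). Fry called 0 for shRad21_1 and 11, 15 and 3 for the others, and removal of the 2 first libraries gave 6 for the mean; the cause was not tested. Each library left out gave 2 to 2, 7 to 13, 13 to 17 and 2 to 7 lists. Genes called in a comparison had passed a threshold, and most named genes had groups without overlap. A reversal of either was thus unlikely from the start. Of 178 results on 123 named genes, 178 never reversed. With 1 library left out 971 such values kept their side of the threshold, 96 lost the call and 1 gained it; 47 lost it with close pairs summed, 17 with limma-voom and 6 with 2 groups in the fit. Depth limits genes with a few counts per library, where 3 counts are at most 0.0863 CPM. On simulated data with independent libraries edgeR recovered 47.8% of 1.5-fold changes, so smaller changes are likely undercounted.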

Other observations

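In this part, the choice of Calb2 and Hydin, of the genes moving in opposite directions and of the gene families, and the test of cluster position without each library, were made only after the values were seen. The tests of gene span, neighbouring genes and position in the protocadherin cluster were set beforehand.

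Some gene families, taken as genes sharing a symbol stem, had more members called under shRad21_2 than a draw of independent genes gives. The test takes genes as independent, and no test with an estimated correlation was run. Of 54 translation initiation factor genes (Eif) 34 were called higher and 6 lower (edgeR, adjusted p = 4.61e-09 by a hypergeometric test over 147 stems). Also higher were 14 of 20 nucleoporins (Nup, adjusted p = 2.61e-04), 20 of 36 helicases (Ddx, adjusted p = 2.98e-04), 20 of 39 ubiquitin enzymes (Ube, adjusted p = 0.00109), 8 of 10 exosome genes (Exosc, adjusted p = 0.00341) and 14 of 28 RNA polymerase genes (Polr, adjusted p = 0.0160). Members that fell were Ddx58 (-1.15), Ube2l6 (-1.44), Ube2h (-0.34) and Ube2w (-0.32; not called without shNT replicate 1 or 2 or shRad21_2 replicate 3, -0.36 to -0.27). In the order given, median log2 fold changes were small, at 0.27, 0.30, 0.25, 0.27, 0.42 and 0.26. With library totals only the counts were 21, 10, 16, 13, 6 and 10. Without shNT replicate 2 they were 20, 8, 15, 12, 6 and 9, and without shNT replicate 3 they were 22, 8, 16, 13, 8 and 9. The ubiquitin enzymes were also 13 without shRad21_2 replicate 3. With close pairs summed, chosen after seeing the data, they were 13, 6, 12, 9, 5 and 6.

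Families lower under shRad21_2 changed by more. Of 17 cytochrome P450 genes (Cyp) 13 fell and 0 rose (median -0.75, adjusted p = 5.22e-04). Of 32 collagens (Col) 16 fell (-0.99, adjusted p = 0.0168), while Col28a1 (3.72), Col6a4 (2.23), Col27a1 (1.21) and Col23a1 (1.04; not called without shNT replicate 2 or 3, 0.81 to 1.35) rose. Of 16 aldehyde dehydrogenases (Aldh) 10 fell (-0.70, adjusted p = 0.0168) and Aldh1a1 rose (2.95). Of 10 carbonic anhydrases (Car) 7 fell (-1.40, adjusted p = 0.0385; 4 without shNT replicate 2 or 3 or shRad21_2 replicate 2) and Car12 rose (3.07). Of 34 Gpr receptors 17 fell (-0.59, adjusted p = 0.0156) and Gpr153 rose (1.41). Of 23 interleukins and their receptors (Il) 13 fell (-0.91, adjusted p = 0.0156). Il17d (2.19), Il17ra (1.40) and Il15ra (0.92) rose, as did Il25 (1.52) and Il20rb (0.68). The last 2 were not called without any of the shNT libraries or without shRad21_2 replicate 2, nor Il25 without shRad21_2 replicate 1 and Il20rb without replicate 3 (1.0 to 1.84 and 0.52 to 0.83). With close pairs summed, the counts that fell were 8 for Cyp, 14 for Col, 8 for Aldh, 4 for Car, 13 for Gpr and 11 for Il. The single genes named in these families were chosen after their values were seen.

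Under shRad21_1 the 2 families past the test were protocadherin beta (10 of 21 higher, adjusted p = 5.25e-07) and RING finger genes (Rnf, 10 of 70 higher, adjusted p = 0.0465). The risen RING finger genes were 2 without shNT replicate 2 or 3, 6 without shNT replicate 1 or shRad21_1 replicate 3, 5 without shRad21_1 replicate 2, and 0 with close pairs summed. Rnf43 (-1.64), Rnf144b (-1.37) and Rnf32 (-0.71) fell, with calls lost without shNT replicate 2 or 3, and for Rnf43 and Rnf144b also without shNT replicate 1 or shRad21_1 replicate 2, and for Rnf144b without shRad21_1 replicate 3 (-1.97 to -1.44, -1.60 to -1.18 and -0.80 to -0.65).

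Among the genes moving in opposite directions, Lbh was at 0.58 under shRad21_1 and -0.36 under shRad21_2, and Sord at -0.62 and 0.43. They and 4930453N24Rik (-0.56 and 0.37) were the 3 that remained without shNT replicate 2 or 3, and 0 remained with close pairs summed, chosen after seeing the data. The largest difference among the 16 was that of Fam19a2 (0.94 and -2.40). The 2 genes with the largest rises under shRad21_2, Calb2 and Hydin, lie 98.8 kb apart on chromosome 8 with 1 tested gene between them.

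Neighbouring genes changed slightly more alike than genes in shuffled order. Log2 fold changes of adjacent genes had a rank correlation of 0.0762 under shRad21_1 and 0.0846 under shRad21_2, over 10838 pairs after pairs sharing a symbol stem were left out. The highest of 1000 shuffles of gene order were 0.0340 and 0.0264. The correlations are weak, run across genes, which are not independent replicates, and both rest on the same shNT libraries. No comparison without a knockdown was run as a baseline, so the values do not tie the likeness of neighbours to low Rad21.

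Position in the protocadherin beta cluster is a candidate explanation for which of its genes rose. Log2 fold change fell with start along chromosome 18 (21 genes, 37294812 to 37524479), with a rank correlation of -0.64 under shRad21_1 (permutation p = 0.00231) and -0.62 under shRad21_2 (permutation p = 0.00341). The permutation takes the genes of the cluster as independent, which neighbouring genes may not be. Its p-values measure spread across genes and not between libraries. Relative to the mean of shNT the correlation was -0.723, -0.564 and -0.555 in the shRad21_1 libraries, -0.732, -0.308 and -0.551 with shRad21_2, and -0.587, 0.414 and 0.394 in shNT. The shNT libraries thus also differ from each other along the cluster without a knockdown; centring on their mean makes their signs oppose, so these values do not show which of them departs. Without each library in turn it ran from -0.683 to -0.557 under shRad21_1 and from -0.727 to -0.492 under shRad21_2. Both hairpins share the shNT libraries, so the 2 values are not independent.

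A fall of long genes under both hairpins, the form set beforehand, was not borne out. The rank correlation of log2 fold change with gene span was 0.0392 under shRad21_1 and -0.0671 under shRad21_2. It was -0.030 under shRad21_2 when genes over 2-fold lower were left out. Leaving out fallen genes takes away part of any such fall, so that value does not speak against it. Under shRad21_2, 32.8% of genes over 100 kb were called lower and 17.8% higher, against 19.4% and 22.8% of genes under 20 kb. Long genes were thus called lower more often with that hairpin. Under shRad21_1 the shares were 9.09% lower and 6.75% higher over 100 kb, against 4.74% and 3.42% under 20 kb. There long genes were called more often in both directions.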
